A study of Homo sapiens with 14 samples.

How the data were processed

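CpG methylation at the TEAD4 promoter was measured by targeted bisulfite amplicon sequencing in 14 libraries of HGC-27, a human gastric carcinoma cell line. Bisulfite treatment turns unmethylated cytosine into a base read as thymine, so that the share of reads still showing cytosine gives the methylation level of a site. The libraries form 7 groups of 2: untreated cells, edited cells on days 3, 7 and 14 after transfection, and gRNA-only cells on the same 3 days. Edited cells are, per the labels, HGC-27 cells of a KRAB line that received the DNMT3AL domain together with 7 guide RNAs. KRAB is a transcriptional repressor domain of zinc finger proteins, DNMT3A is a de novo DNA methyltransferase, and DNMT3L is its catalytically inactive cofactor. The gRNA-only cells are HGC-27 cells that received the 7 guide RNAs alone, so the arms differ in both the KRAB line and the DNMT3AL domain. Groups and replicate numbers were taken from the labels, which place every library in 1 batch and do not say whether replicates were separate cultures.

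Amplicons were pooled in equal molar amounts per sample and sequenced with an aim of at least 100000 reads per amplicon, per the labels' protocols. Reads were handled with Trim Galore 0.6.7, a read trimmer, and Bismark 0.23.1, a bisulfite aligner and methylation caller, on the hg38 build, per the submitters' processing notes. How these calls were turned into the deposited table is not given in the sources used here. The deposited values are methylation levels in percent, written with decimal commas, at 157 CpG positions on chromosome 12, and every library lists the same positions. No read count or coverage per site was used here, so the depth behind each value is unknown and no counting interval or detection limit is given. Compared site by site at the full precision deposited, the highest number of identical values between any 2 libraries was 0.

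A count test per site had been chosen before the data were examined, together with the comparisons, site groups and alternatives. It needs read counts and was replaced by limma on log2((percent + 0.1)/(100 − percent + 0.1)), fitted to all 157 sites and 14 libraries with 1 mean per group and empirical Bayes moderation. This choice was made after the unit was known. Benjamini-Hochberg adjusted p-values were taken over the 157 sites with a threshold of 0.05. The all-days comparison is the mean of the 3 within-day differences. Levels and differences are given in percentage points, as mean ± SD over libraries. The SD over the 6 libraries of an arm covers 3 days.

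For region means, each library's unweighted mean over sites was compared by a two-sided exact permutation test, within days for edited against gRNA-only cells. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so single days carry no p-value for the region mean. Site groups were runs of sites with no gap above 100 bp, sites before and after the annotated start of TEAD4, and sites with an untreated mean under 10%, from 10 to 50% and over 50%. Named sites followed a fixed rule: for all days the 10 sites with the largest change per direction past the threshold and with 1 sign on the 3 days, for each single day 3 per direction, for other comparisons 5 per direction, and the 3 largest differences where no site passed. Gene positions come from the RefSeq gene table of GRCh38, whose chromosome coordinates are shared by its patch releases. Exon, intron and UTR annotation was not used here. A finer division into 7 stretches of sites that moved together was made after the values were seen, by least-squares segmentation. Tests on these stretches are given only in the closing section and were made on the values that defined them.

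Alternatives were a quasi-binomial logistic regression with an F-test per site, a replicate block, a minimum difference of 5 percentage points, the median over sites or the mean of run means in place of the mean, and leaving out each library in turn. The quasi-binomial regression was first run with a Wald test, which was replaced by the F-test chosen in advance after its counts had been seen; the Wald counts are kept as an added alternative. Also added after the values were seen were offsets of 1 and 0.01, limma on untransformed percent, limma with a variance trend, leaving out the sites above 90% in every library, leaving out 3 libraries chosen by eye for raised levels, and leaving out the 4 control libraries with a stretch above 3%. The fit was tested on simulated data for the all-days comparison, with 60 of 157 sites changed in each of 50 simulations. It recovered 22.4% of sites shifted by 1 on the log2 odds scale, 86.3% of those shifted by 3 and 98.2% of those shifted by 5. Of the simulated calls 4.2% were false, with up to 44 false calls in 1 simulation. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.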

Results

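Methylation levels were obtained at 157 CpG sites on chromosome 12 (GRCh38) in untreated HGC-27 cells, in cells given the DNMT3AL domain with 7 guide RNAs (edited cells), and in cells given the guides alone (gRNA-only cells). TEAD4 encodes a TEA domain transcription factor that binds the YAP and TAZ coactivators of the Hippo pathway. Its gene spans 2959397 to 3040676, and it lies on the forward strand. The sites fell into 6 runs: run 1 from 2958885 to 2959590 (100 sites), run 2 from 2959762 to 2960007 (38 sites), run 3 from 2960239 to 2960277 (4 sites), run 4 from 2963587 to 2963671 (4 sites), run 5 at 2963792 (1 site) and run 6 from 2964125 to 2964284 (10 sites). Before the gene's start lay 64 sites, all in run 1, and 93 sites lay inside the gene. An uncharacterised long non-coding RNA gene, LOC124902859, spans 2957598 to 2960048 and covers 138 of the sites. Each group held 2 libraries, the depth per site is unknown, and p-values measure only the spread between these libraries, which may be technical.

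The series asks whether methylation was placed on the TEAD4 promoter, which the comparison of edited with gRNA-only cells of the same day addresses. Edited cells carried more methylation around the TEAD4 start. Averaged over the 157 sites, the level was 31.4% ± 4.87 (SD, n = 6) in edited and 15.6% ± 1.71 (SD, n = 6) in gRNA-only cells, and each edited library (23.3 to 37.0%) lay above each gRNA-only library (14.5 to 19.0%). The difference of 15.7 percentage points had an exact within-day permutation p of 0.00926, the smallest that this design allows. The exact and limma p-values here and below treat the libraries of an arm as independent across days. The labels do not settle this, and the gRNA-only libraries may not be independent. Single sites followed: 134 of 157 rose and 0 fell at a limma adjusted p under 0.05. Limma on untransformed percent called 125 rises and 1 fall, quasi-binomial regression 136 and 1, and its Wald test 130 and 1.

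The rise seen lay in the 3 runs around the start, and the runs farther into the gene stayed near full methylation in every group. These far runs had almost no room to rise, so they cannot show whether the rise was confined to the start. In run 1, 93 of 100 sites rose, and the mean was 21.3% ± 6.22 in edited against 7.67% ± 0.864 in gRNA-only cells (SD, n = 6 each). The 33 sites between 2959403 and 2959566 were among the 93, but none of them passed limma's threshold on any single day. In run 2, 37 of 38 sites rose, with means of 33.2% ± 9.70 and 5.73% ± 5.75 (SD, n = 6 each). All 4 sites of run 3 rose, from 3.92% ± 4.75 in gRNA-only to 21.2% ± 6.66 in edited cells (SD, n = 6 each); gRNA-only replicate 1 had 9.94% on day 3 and 10.2% on day 7, and the other 4 gRNA-only libraries had 0.767 to 0.941%. None of the 15 sites of runs 4 to 6 passed limma's threshold (0 sites, with 0 unadjusted; quasi-binomial regression called 1, with 2 unadjusted), and their run means lay between 94.3 and 98.4% in all 14 libraries. By two-sided exact permutation within days, adjusted over 11 site groups, the run differences were 13.6 points (adjusted p = 0.017), 27.5 points (adjusted p = 0.0291) and 17.3 points (adjusted p = 0.017) for runs 1 to 3. For runs 4, 5 and 6 they were -0.293, -0.517 and -0.394 points, with exact adjusted p from 0.275 to 0.361. In run 2 the gRNA-only library of day 3 replicate 1 had a mean of 17.5%, while the other gRNA-only libraries had 3.25 to 3.62%.

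Most of the sites that rose had been low in untreated cells. Of the 131 sites under 10% in untreated cells, 130 rose, also when adjusted over the list alone, and their mean was 18.2 points higher in edited cells (exact adjusted p = 0.017). Among the 4 sites from 10 to 50%, 2 rose, also when adjusted over the list alone, with a group difference of 17.6 points (exact adjusted p = 0.017). Of the 22 sites over 50%, 2 rose and 0 passed when adjusted over the list alone, with a group difference of 0.897 points (exact adjusted p = 0.275). Among all sites, 18 were above 90% in every library and had little room to rise. Before the TEAD4 start 58 of 64 sites rose, with a group difference of 14.4 points, and inside the gene 76 of 93 rose, with 16.7 points (exact adjusted p = 0.017 for both).

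The 10 sites with the largest rise were 9 sites of run 2, between 2959772 and 2959979, and 1 site of run 1, 2959124. At CpG 2959921, which lies 524 bp into the gene, methylation was 71.5% ± 18.5 (SD, n = 6) in edited, 6.11% ± 12.8 (SD, n = 6) in gRNA-only and 0.967% ± 0.325 (SD, n = 2) in untreated cells. The gRNA-only mean rests on day 3 replicate 1, at 32.3%, since the other 5 libraries lay between 0.62 and 1.27%. This rise of 65.4 points corresponded to 7.29 ± 0.76 (SE) on the log2 odds scale, with a limma adjusted p of 4.91e-05. CpG 2959979 rose by 61.7 points and CpG 2959923 by 60.7 points. At CpG 2959124, at -273 bp from the start, the level was 52.8% ± 19.9 in edited (SD, n = 6) and 0.921% ± 0.204 in gRNA-only cells (SD, n = 6). The remaining sites of the 10, 2959913, 2959906, 2959902, 2959772, 2959893 and 2959875, rose by 47.7 to 59.8 points. Limma adjusted p-values of the 10 sites lay between 4.91e-05 and 5.15e-05. Without 3 libraries chosen by eye for raised levels, edited day 3 replicate 2, gRNA-only day 3 replicate 1 and untreated replicate 2, 130 sites rose. Without the 4 control libraries that held a stretch above 3%, gRNA-only replicate 1 of each day and untreated replicate 2, 129 rose. Removing control libraries for their high stretches widens the difference there by construction, and it left 1 library in each control group, assumed to vary like the other groups.

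**Figure D1:**
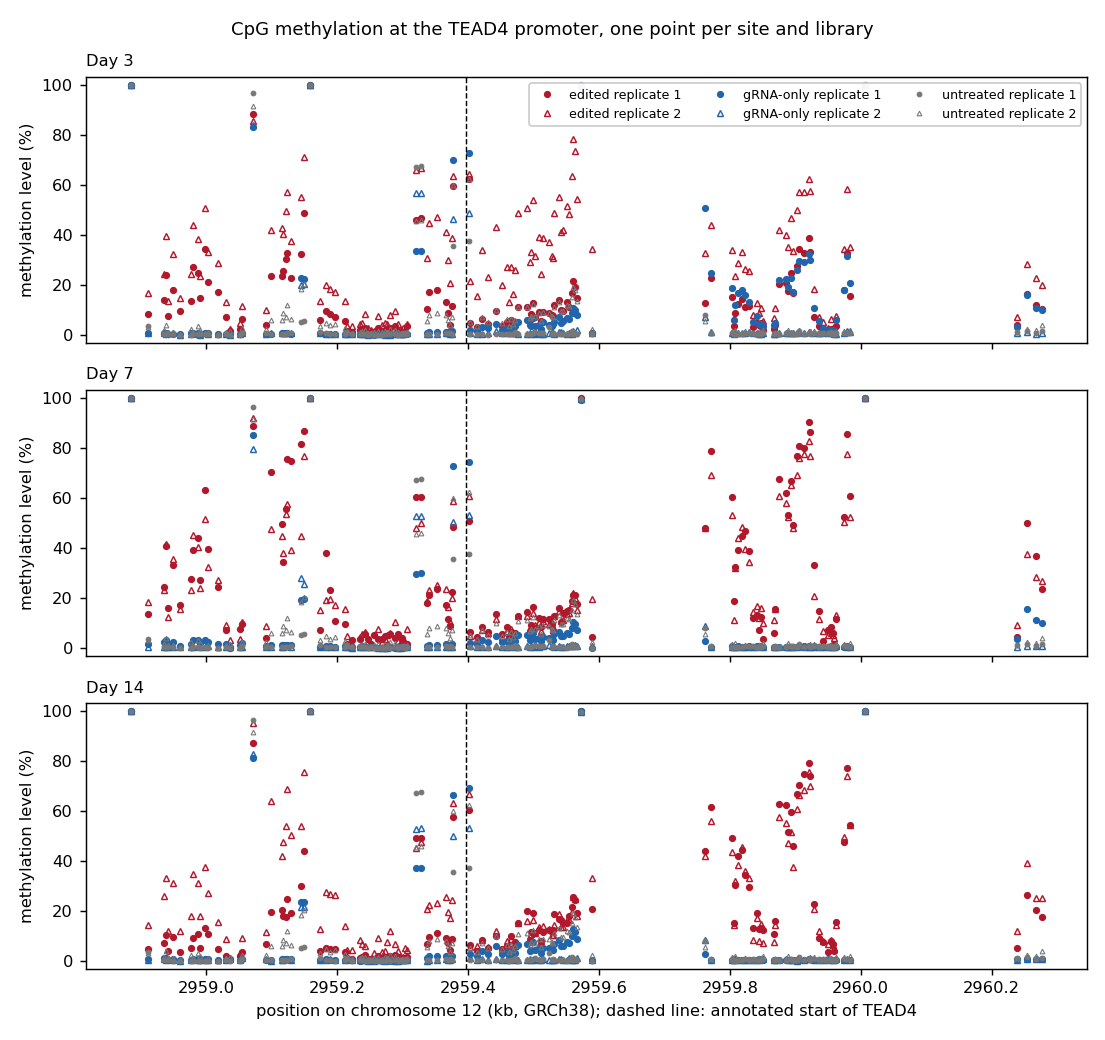
Methylation level in percent against position on chromosome 12 in kb for runs 1 to 3, with a panel per day and a point per site and library; the untreated libraries are repeated in each panel and the dashed line marks the annotated start of TEAD4. Most edited points stand above the controls on both sides of the start, up to 90.2% at CpG 2959921. Exceptions include run 2 on day 3, where gRNA-only replicate 1 (mean 17.5%) exceeds edited replicate 1 (15.7%), and the sites from 2959320 to 2959328 and from 2959377 to 2959401, where control libraries reach pair means of 67.4 and 73.5%.

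The time course asks when methylation appeared and whether it was still there on day 14. On day 3 the edited cells averaged 30.2% ± 9.72 over all sites and gRNA-only cells 16.8% ± 3.09 (SD, n = 2 each). On day 7 the levels were 33.5% ± 0.988 and 15.1% ± 0.783, and on day 14 they were 30.5% ± 3.12 and 15.0% ± 0.75 (SD, n = 2 each). The within-day differences were thus 13.4, 18.4 and 15.4 points, each larger than the pooled SD of its groups (7.21, 0.891 and 2.27 points), although an exact test of 2 libraries against 2 cannot go below 0.333. The day 3 difference was 6.50 points without edited replicate 2 and 20.2 points without edited replicate 1. With the 6 runs weighted equally, the differences of days 3, 7 and 14 were 6.36, 11.9 and 10.4 points, and that over all days was 9.54 points (exact permutation p = 0.00926).

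On day 3, 47 sites rose and 0 fell at a limma adjusted p under 0.05, and all 47 lay in run 1 before the TEAD4 start. These calls alone do not place the rise upstream. The median difference was 10.3 points over the 64 sites before the start and 11.8 over the 93 inside the gene. The gRNA-only libraries had means of 26.65 and 19.1% inside the gene, but of 7.78 and 8.03% before the start. The largest rises on that day were at CpG 2959124 (44.0 points), CpG 2958998 (41.8 points) and CpG 2959122 (38.9 points). Without edited replicate 2, CpG 2959124 and CpG 2959122 no longer passed (31.7 and 29.4 points, limma adjusted p = 0.0689 for both), nor did they on untransformed percent (limma adjusted p = 0.0826 and 0.054). On day 7, 95 sites rose and 0 fell, of which 55 lay in run 1, 37 in run 2 and 3 in run 3. On day 14, 89 sites rose and 0 fell, of which 48 lay in run 1, 37 in run 2 and 4 in run 3. Limma with a variance trend and quasi-binomial regression each called 1 fall on day 14. CpG 2959921, CpG 2959979 and CpG 2959923 led on both later days, with rises of 85.8, 81.1 and 81.0 points on day 7 and 76.6, 74.9 and 71.4 points on day 14. The day 3 count depended on single libraries: it was 3 without edited replicate 2, 23 without gRNA-only replicate 2 and 94 without gRNA-only replicate 1, it was 108 without the 4 control libraries named above, and it was 9 with limma on untransformed percent and 25 with quasi-binomial regression. For day 14, 50 sites passed without edited replicate 2 and 52 on untransformed percent. A quasi-binomial Wald test ended nearly all single-day calls, with 0, 1 and 1 sites on days 3, 7 and 14 (31, 71 and 52 unadjusted), while it called 131 sites over all days.

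Run 2 of the edited cells averaged 22.1% ± 9.07 on day 3, 40.4% ± 1.47 on day 7 and 37.2% ± 1.59 on day 14 (SD, n = 2 each). Its gRNA-only libraries had 17.5 and 3.62% on day 3, and means of 3.33% ± 0.055 on day 7 and 3.32% ± 0.098 on day 14 (SD, n = 2 each). In run 1 the edited cells had 23.8% ± 11.6, 21.6% ± 0.823 and 18.4% ± 5.34 (SD, n = 2 each). Over all sites the edited cells of day 14 differed from those of day 3 by 0.323 points, less than the pooled SD of 7.22 points. No site passed the limma threshold between these days (0 sites, with 2 at an unadjusted p under 0.05; quasi-binomial regression called 0, with 13 unadjusted). The largest differences, none past the threshold, were 29.96 points at CpG 2959979, 29.1 points at CpG 2959875 and 29.0 points at CpG 2959984 (limma adjusted p = 0.894 for each). Tested directly, the change from day 3 to day 14 differed between edited and gRNA-only cells at 0 sites with limma (31 unadjusted) and 0 with quasi-binomial regression (32 unadjusted). Edited day 3 replicate 2 had 37.0% over all sites and replicate 1 had 23.3%, so leaving out replicate 2 lowers the edited day 3 mean by construction. Leaving out gRNA-only day 3 replicate 2 keeps only replicate 1, at 17.5% in run 2, which raises the day 3 control by construction. Without the 3 libraries named first above, which left 1 edited and 1 gRNA-only library on day 3 that were assumed to vary like the other groups, these counts were 28 between days and 20 for the difference of changes; the latter was 35 without gRNA-only day 3 replicate 2. Without the 4 control libraries both counts were 0 with limma (7 and 2 unadjusted).

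**Figure D2:**
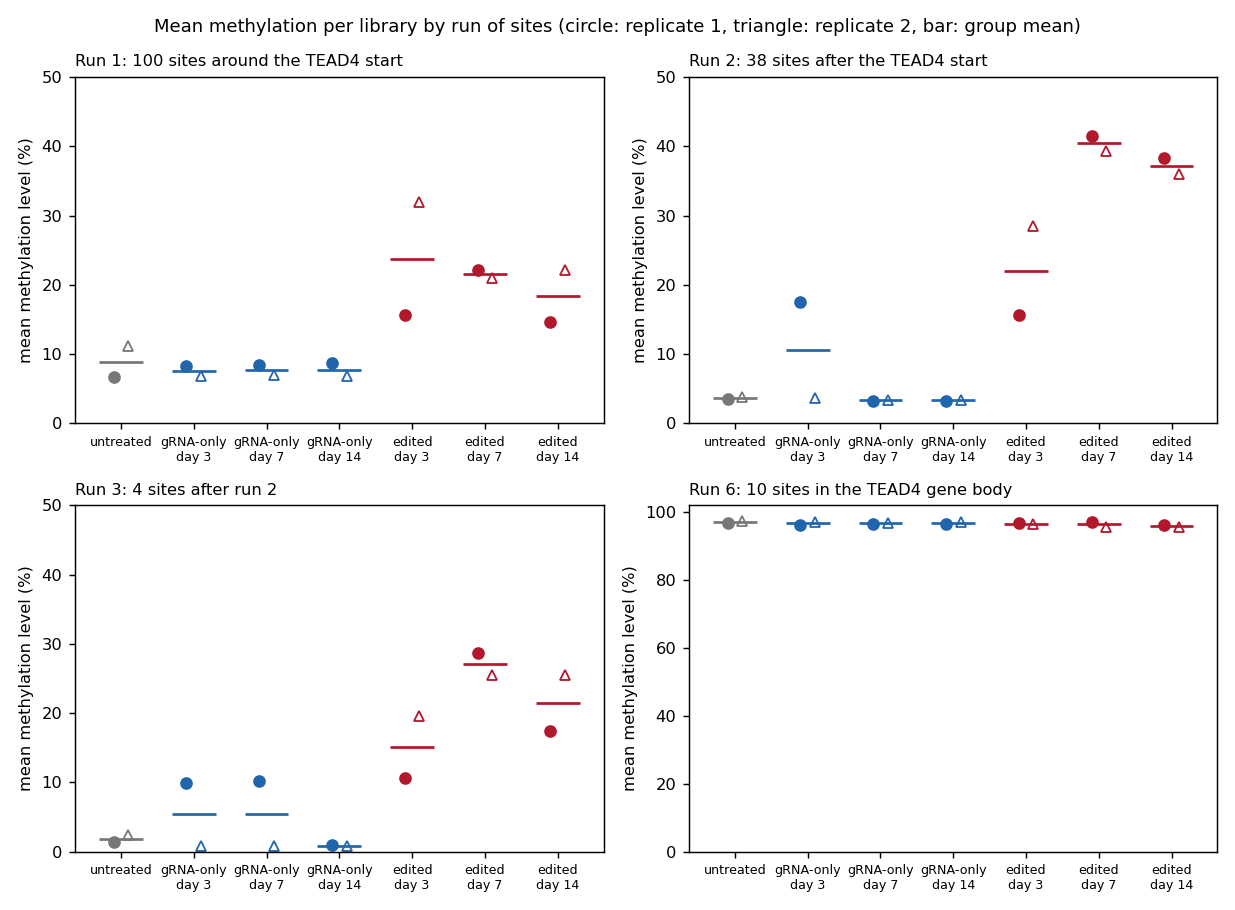
Mean methylation level in percent per library for runs 1, 2, 3 and 6, by group; circles are replicate 1, triangles replicate 2, and bars the mean of the 2 libraries. In run 2 the edited libraries reach 36.0 to 41.5% on days 7 and 14, while run 6 lies between 95.6 and 97.3% in every library.

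Untreated cells served as a further control. They averaged 15.9% ± 2.12 over all sites (SD, n = 2), 15.5 points below the edited cells, with a two-sided exact permutation p of 0.0357, the smallest that 2 against 6 libraries allow. At a limma adjusted p under 0.05, 91 sites rose in edited over untreated cells and 0 fell, of which 50 lay in run 1, 37 in run 2 and 4 in run 3. The largest rises were 70.5 points at CpG 2959921, 66.8 points at CpG 2959979, 65.3 points at CpG 2959923, 64.4 points at CpG 2959913 and 62.9 points at CpG 2959906 (limma adjusted p = 0.000522 for each). Between 2959403 and 2959566, directly after the start, 0 of 33 sites passed with limma (5 unadjusted) and 0 with quasi-binomial regression (0 unadjusted); there the untreated libraries had means of 0.644 and 9.10% and the edited libraries 9.21 to 38.6%. Without untreated replicate 1, 51 sites rose and 0 fell, and without untreated replicate 2, 121 rose and 1 fell. A quasi-binomial Wald test called 1 site in this comparison, with 68 unadjusted.

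Whether the guides alone altered methylation was asked by setting gRNA-only against untreated cells. The means over all sites, 15.6% ± 1.71 (SD, n = 6) and 15.9% ± 2.12 (SD, n = 2), differed by -0.233 points (two-sided exact permutation p = 0.964). No site passed the limma threshold (0 sites, with 3 at an unadjusted p under 0.05; quasi-binomial regression called 0, with 1 unadjusted). The largest differences, none past the threshold, were -12.9 points at CpG 2959328, -12.6 points at CpG 2959320 and 12.1 points at CpG 2959401 (limma adjusted p = 0.994 for each). Control libraries nonetheless differed in stretches. Between 2959403 and 2959566, replicate 1 of the gRNA-only cells had 4.74, 4.48 and 5.60% on days 3, 7 and 14, and replicate 2 had 0.812, 0.711 and 0.681%. The 6 gRNA-only libraries may thus not be independent of one another.

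**Figure D3:**
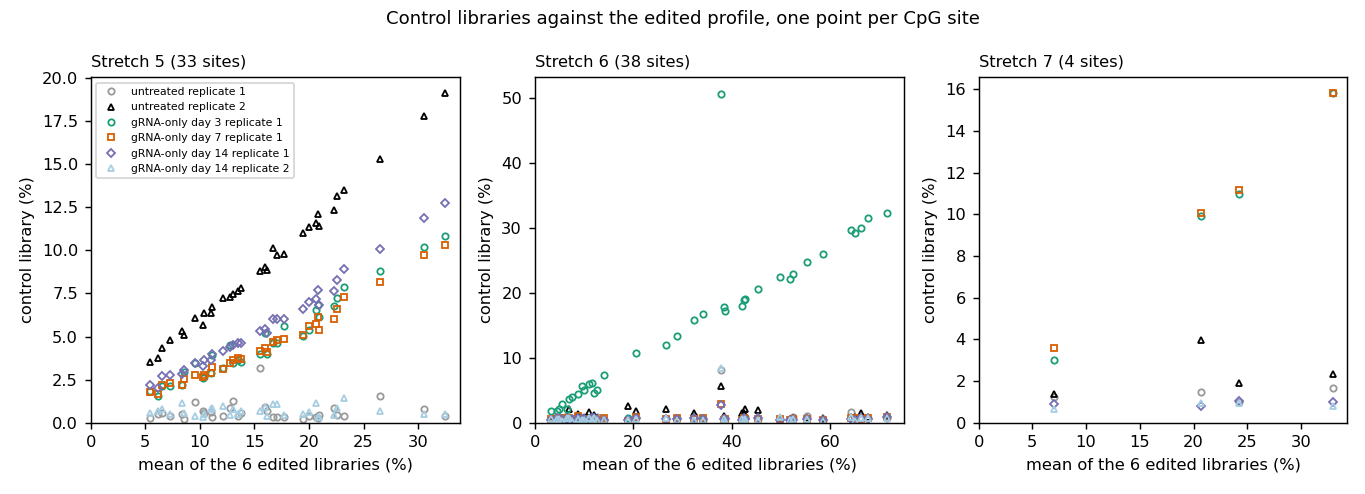
Methylation level in percent of 6 control libraries against the mean of the 6 edited libraries, with a point per CpG site, in 3 stretches of sites: stretch 5 from 2959403 to 2959566, stretch 6 from 2959590 to 2959984 and stretch 7 from 2960239 to 2960277. In stretch 5 untreated replicate 2 and the gRNA-only replicate 1 libraries rise with the edited level, while in stretch 6 gRNA-only day 3 replicate 1 does so, to a stretch mean of 14.8%.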

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

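All tests weighed here were chosen after the values were seen, as were the stretches and the limit of 3% above which a stretch counts as raised. Among the 6 gRNA-only libraries, day 3 replicate 1 stood apart in its mean over all sites, with 18.959% against 14.5 to 15.6% in the others, a gap of 0.745 of the whole range. The same library stood apart in run 2, with 17.462% against 3.25 to 3.62% and a gap of 0.974 of the range. Both gaps exceed the 95% critical value of Dixon's test for 6 libraries; 14 sets of 6 libraries were examined, and chance exceeds it in about 1 set in 20.

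The library is part of a wider pattern: of 40 combinations of 8 control libraries and 5 stretches, 9 were raised, in gRNA-only replicate 1 of each day and in untreated replicate 2. Edited DNA or cells mixed into a whole sample would raise every stretch to the same share of the edited profile. In each of the 4 raised libraries the shares differed, by at least 0.387 and by more than 2 standard errors over sites. That test cannot weigh the mixing, since the stretches were cut on these same profiles and sites are not independent replicates. In run 2, a group fixed in advance, edited cells averaged 33.2%. There gRNA-only replicate 1 of days 7 and 14 and untreated replicate 2 had 3.25 to 3.76%, and control libraries with no raised stretch had 3.365 to 3.623%. These values argue against whole-sample mixing for those raised libraries. Guides alone are argued against by the gRNA-only replicate 2 libraries, at most 1.01% in stretches 5 to 7, while untreated replicate 2 reached 9.10%. For incomplete bisulfite conversion a first test left the question open, since the excess at the sites lowest in edited cells was a median of 0.303 of that at the highest sites but reached 0.596 in 1 stretch; a second test, added after that outcome, found that each raised library also held a stretch at or below 1.25%, which argues against failed conversion of a whole library but not of single stretches. Across sites, which are not independent replicates, the excess followed the edited profile with a median Pearson r of 0.988 over the raised stretches (lowest 0.456). Over the others the median was 0.017, but r ran from -0.874 to 0.96, so the 2 sets overlap. A candidate explanation is that molecules from edited samples entered single amplifications. A gain of methylation in the control cultures themselves, limited to those stretches, stays open and was not tested.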

How the results depend on the processing

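The tests of splits, the offsets, the untransformed, trended and Wald fits and the omission of sites or of 3 or 4 libraries were chosen after the values were seen. Across the alternatives no result changed direction past its threshold. Of the values that answer a comparison 201 were counted as unchanged, 4 moved, 5 became stronger and 16 weaker. Of those for named sites 699 were counted as unchanged, 3 became stronger and 18 weaker. Unchanged here allows for shifts in size and, for differences not past a threshold, in sign. Over all sites, the edited day 3 mean was 37.0% without replicate 1 and 23.3% without replicate 2, against 30.5% on day 14. The gRNA-only mean of 15.6% lay between untreated replicates 1 and 2, at 14.4 and 17.4%. The signs of both differences thus depended on single libraries. Over all days 123 to 137 sites passed, apart from 108 with a minimum of 5 points, and 123 to 134 of them were among the 134; of 100 splits of the libraries within days (108 exist) only the real one reached 134, the highest other giving 109, which argues against chance. The day 7 difference was 16.7 as a median over sites, 11.9 as a mean of run means and 20.8 without sites above 90%; as means of run means those of days 3, 14 and all days were 6.36, 10.4 and 9.54. The day 3 count was 9 untransformed and 25 by quasi-binomial regression, and 3 to 94 with a library left out (3 without edited replicate 2, 23 without gRNA-only replicate 2, 94 without gRNA-only replicate 1). The day 14 count was 52 untransformed and 50 to 91 with a library left out (50 without edited replicate 2). By the quasi-binomial Wald test 0, 1 and 1 sites passed on days 3, 7 and 14, 1 between edited and untreated cells and 131 over all days, and none of the named sites of the single days or of edited against untreated cells did (adjusted p from 0.0841 to 0.173). Edited against untreated cells gave 51 to 122 sites with a library left out (51 without untreated replicate 1) and differences of 14.0 to 17.1 points; with 1 untreated library left (14.0 and 17.0) the exact test cannot reach the threshold. Leaving out the 3 libraries gave 15.9 points there (exact p = 0.167, fewer samples), 28 sites between days 14 and 3 and 20 for the difference of changes; the latter was 0 to 35 with a library left out (35 without gRNA-only day 3 replicate 2). Leaving out the 4 raised control libraries gave 108 sites on day 3, 129 over all days and 17.0 points over untreated cells (exact p = 0.143, fewer samples), and -1.08 points at the 1 site of run 5 (unadjusted exact p = 0.037, the smallest possible). Where no construction is named here or in the results above, the cause was not tested. With a replicate block the difference of edited from untreated cells stayed at 15.5 and that of run 2 at 27.5 points. Both had an exact permutation p of 0.0625, for the former the smallest the block allows. No other call changed, with 133 sites over all days. Correlations of deviations over the 21 pairs of groups ran from -0.727 to 0.751, so the replicate number does not pair all groups alike. Pairs of edited with control groups were not examined separately. Among the 3 gRNA-only groups the correlations ran from 0.246 to 0.751, so there the number links libraries across days. Coverage minimums, coverage weighting and merging of strands could not be run. The depth is unknown, so how far it limits the results could not be examined.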

Other observations

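The tests of explanations in this part were all chosen after the values were seen. Beyond the comparisons, the region held a sharp division: 18 sites were above 90% in every library, and runs 4 to 6, from 4190 to 4887 bp into TEAD4, held 15 sites with run means from 94.3 to 98.4%. Within the promoter, 4 sites chosen after their values were seen were near full methylation in every library. CpG 2958885, CpG 2959159, CpG 2959572 and CpG 2960007 ranged from 99.3 to 100.0%. Each of their direct neighbours averaged at most 19.9% over the 8 control libraries. Single control libraries could lie higher, with 25.7% at the neighbour CpG 2959150 in gRNA-only day 7 replicate 2. CpG 2959071, also chosen afterwards, is among the sites that rose (6.84 points over gRNA-only cells, limma adjusted p = 0.048), yet its level was 94.0% ± 3.45 in untreated (SD, n = 2), 89.4% ± 3.46 in edited (SD, n = 6) and 82.6% ± 1.98 in gRNA-only cells (SD, n = 6). The neighbours CpG 2959145 and CpG 2959150 were at intermediate levels in gRNA-only cells, 22.6% ± 3.05 and 22.2% ± 2.20 (SD, n = 6), and rose to 49.6% ± 18.8 and 67.1% ± 17.0 in edited cells (SD, n = 6).

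By stretch, the exact within-day permutation test of edited against gRNA-only cells, adjusted over 7 stretches, gave 15.0 points from 2958911 to 2959306, 18.3 points from 2959337 to 2959375, 12.9 points from 2959403 to 2959566 and 17.3 points from 2960239 to 2960277 (adjusted p = 0.0162 for each). Without edited day 3 replicate 2, at 38.6%, the difference from 2959403 to 2959566 was 7.97 points (unadjusted exact permutation p = 0.0093), and its call was lost without gRNA-only day 3 replicate 1 (p = 0.0741) or replicate 2 (p = 0.0926). From 2959590 to 2959984 it gave 27.98 points (adjusted p = 0.0259). A pair of sites at 2959320 and 2959328 gave 9.06 points (adjusted p = 0.227), and a pair at 2959377 and 2959401 gave -0.858 points (adjusted p = 0.88), neither past the threshold. With a library left out the former fell to 5.17 points without gRNA-only day 3 replicate 1, 5.20 without gRNA-only day 7 replicate 1 and 5.74 without edited day 3 replicate 2, and the latter ran from -4.82 to 3.10 points.

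Those pairs, which lie on both sides of 7 sites that are low in control cells, moved against each other. In the 8 control libraries the mean of the first pair ran from 29.7 to 67.4% and that of the second from 36.5 to 73.5%, with Pearson r = -0.996 (exact permutation p = 2.5e-05, the smallest the pairings can give), Spearman rho = -1.0 (exact permutation p = 5e-05) and r = -0.995 (exact permutation p = 0.0014) without the 2 libraries farthest from the median, in 1 relation computed. The pairs were cut out and chosen on these same values, and the p-values take no account of that choice. A single batch shared by all libraries of 1 replicate number is argued against, since replicate 1 was lower at the first pair in 4 of 7 groups and the difference of replicate 2 from replicate 1 was -21.55 points in untreated cells, but it was 23.3, 23.2 and 15.8 points in gRNA-only cells of days 3, 7 and 14, so a shared source within that arm stays open and the 8 libraries may not be independent. The sum of the pairs was 104.7% ± 1.1 (SD, n = 8), with an SD 0.085 times the smaller SD of either pair. That small SD follows from the opposite movement of pairs with like spreads and is no separate test. In edited cells the sum varied more, 112.7% ± 8.75 (SD, n = 6). For the control libraries 2 template versions, for example alleles, in varying proportions between libraries may underlie the levels. Whether the proportions vary in the cells or through amplification stays open, and no biological explanation was tested.

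Replicates of the edited cells differed by stretch. On day 3 the ratio of replicate 2 to replicate 1 had a median of 4.29 over the sites from 2959403 to 2959566 and of 1.85 from 2960239 to 2960277, a difference of 1.22 on the log2 scale against a summed between-site SD of 0.24. On day 14 it was 3.12 from 2958911 to 2959306 and 0.936 from 2959590 to 2959984, a difference of 1.74 on the log2 scale against 0.99. On day 7 the medians lay between 0.927 and 1.08, but single sites differed between the replicates. The between-site SD on day 7 was 1.15 on the log2 scale from 2958911 to 2959306. There CpG 2959145 had 81.4% in replicate 1 and 44.7% in replicate 2. A single share of modified cells per culture would shift all stretches by 1 ratio. These ratios cannot weigh it, since the stretches were cut on the same profiles and the SDs are between sites of 1 pair of libraries. By runs fixed in advance, replicates 1 and 2 of day 14 had 14.7 and 22.2% in run 1, but 38.3 and 36.0% in run 2. On day 3 they had 15.6 and 32.0% in run 1, and 15.7 and 28.5% in run 2. With 1 pair of libraries per day the explanation stays open. Unequal action of the guides along the promoter and unequal amplification of the stretches may both contribute, and neither was tested.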
